A study of Homo sapiens with 9 samples.

How the data were processed

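Total RNA, 100 ng per sample per the labels' protocols, was converted to Cy3-labelled antisense RNA with a low-input amplification kit primed on poly(A) and hybridised to single-colour Agilent 4x44K human arrays. N417 cells were grown in RPMI medium with serum and iPS cells in DMEM with a serum replacement, and N417 fractions were isolated with an antibody to SSEA-1, per the labels' protocols. Per the file headers, arrays were scanned on a G2505C scanner and read with Feature Extraction 10.7.1.1, and the array design is annotated on hg18. The deposited scanner tables hold spot intensity values, of which gProcessedSignal is background-subtracted and detrended within each array by Feature Extraction, per the file headers, with no scaling between arrays. The authors' series matrix holds 40997 probes whose values equal the mean raw median intensity of the probe's spots, about 99.4% of them within 0.51 intensity units. It is thus a linear intensity with neither background correction nor scaling. Its column medians were 272, 406 and 226 for iPS-labelled replicates 1 to 3, 68, 59 and 105 for double-negative-labelled and 132, 129 and 148 for SSEA-1-positive-labelled ones. Flags for background, saturation and outliers were taken as Feature Extraction gave them, per the file headers.

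Of 45015 spots per array, 43376 were not controls and stood for 41000 probes. Spots with an outlier flag were left out, which left 468 probes without a value on at least 1 array, and log2 signals of the spots of 1 probe were averaged. No probe was saturated. Log2 of the processed signal minus the array's 75th percentile over all probes was used as the level. Probe accessions matched 26222 probes to 17721 gene symbols of a RefSeq table (GRCh38.p14, used for names only), and 14778 probes were not matched. A probe was kept when well above background on all 3 arrays of at least 1 group, and each gene was represented by its kept probe with the highest mean level, which left 13312 genes. A choice among probes arose for 4610 genes, and 7354 kept probes had no name. No probe positions are given, since the array's build differs from that of the table. The number detected on all 3 arrays was 23889 probes for iPS-labelled, 23215 for SSEA-1-positive-labelled and 13474 for double-negative-labelled arrays, and 10308 probes were detected on all 9.

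Groups came from the sample labels. Gene tests used limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with 1 coefficient per group over all 9 arrays, and Benjamini-Hochberg adjustment at 0.05. The contrasts were SSEA-1-positive minus double-negative, iPS minus each of these, and iPS minus the mean of both. Lists of 812 genes in 29 groups, 23 of them without a matched probe and 7 matched but without a value on every array, were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of 1 contrast, where at least 5 members were tested. They were pluripotency, SSEA epitope glycosylation, neuroendocrine, neuronal, fibroblast and mesenchymal, epithelial, lung epithelium, haematopoietic, G1/S phase, G2/M phase, immediate early, heat shock, p53 targets and apoptosis, cancer stem cell and drug efflux, Notch, Wnt, TGF-beta with Nodal and BMP, Hedgehog, endoderm and mesoderm, neuroectoderm, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein, cholesterol synthesis, unfolded protein response, antigen presentation, interferon response, cancer-testis antigens, and MYC family and targets. At an estimated correlation no list of any pairwise comparison passed, against 25 list calls at the preset one. Similarity was tested with an exact permutation test. Figures were drawn with matplotlib 3.10.9, and the file list was read with jsonlite 2.0.0.

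The groups, tests, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for SSEA-1-positive against double-negative and for iPS against both groups, the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap, whose probe is well above background throughout the brighter groups and which carry an approved-style symbol. A gene of the contrast with both groups had also to pass against each group. It adds up to 4 called members of each list by size of change, or 2 members where none passed, and POU5F1, SOX2, NANOG, LIN28A, KLF4, MYC, FUT4, FUT9, B3GALT5 and NEUROD1 among 11 fixed genes in every comparison. Some sex-linked genes were left out of it. The text names some of the genes that the rule gives, and some genes that it gives are not reported here and enter no total of named genes under alternatives. Scaling over probes detected on all 9 arrays departed from the fixed choice and was used at first, and the fixed choice, the percentile over all probes, was restored after both sets of counts had been seen. Both are printed, with scaling by the median, quantile normalization, a floor on dim signals, the series matrix values, no filter on dim probes, probes above background on all 9 arrays, every kept probe as the unit, the mean of a gene's probes, a trended prior, separate fits of the groups compared, a fold threshold of 2 and blocks by replicate number, slide and scan day as alternatives. Normexp with an offset of 50 was run on the raw median signals, since the mean-signal column it had been planned for was not in the tables used here. Each array was also left out in turn, where a group left with 2 arrays shares the spread of the others.

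Scan days and slides were read from the file headers. Slide 1 held iPS-labelled replicate 3 and SSEA-1-positive-labelled replicate 1, slide 2 double-negative-labelled replicate 3, slide 3 replicates 1 and 2 of the iPS-labelled and double-negative-labelled groups, and slide 4 SSEA-1-positive-labelled replicates 2 and 3. Scan day was fitted as a fixed block and slide likewise. Each scan day held the groups in equal numbers, so its block leaves the changes as they are and alters only their spread. The methods were tested on simulated data with the real spread of 13312 genes, of which 200 changed. For SSEA-1-positive against double-negative, limma recovered 2% of 2-fold and 40% of 4-fold changes with 2 false calls, for iPS against SSEA-1-positive 3% and 49% with 1, and for iPS against double-negative 2% and 34% with 1, and none had the wrong sign. Small changes are therefore mostly below what 3 arrays per group can call where few genes change. The real comparisons, in the same order, called 11078, 1377 and 11185 genes. The adjusted cutoff is less strict with that many, so these shares do not describe recovery there.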

Results

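Messenger RNA levels were measured on 9 single-colour oligonucleotide arrays, 3 in each of 3 labelled groups. The first group is labelled 253G1, a line of human induced pluripotent stem (iPS) cells. The others are labelled as fractions of N417, a small cell lung cancer line, sorted by flow cytometry. By label the positive fraction carried SSEA-1, a cell-surface carbohydrate also known as Lewis X, and the double-negative fraction carried neither SSEA-1 nor SSEA-3. The design sets iPS cells against each sorted fraction, with 3 replicates per condition described as biological. The labels of the iPS arrays also name N417 as the cell line and fibroblast as the source, so groups are called here by their labels. Probes well above background made up 61.7%, 61.2% and 71.6% of all probes on iPS-labelled replicates 1, 2 and 3, and 67.3%, 59.3% and 61.2% on the SSEA-1-positive-labelled ones. On the double-negative-labelled arrays the shares were 37.2%, 34.2% and 69.7%, and the 75th percentile of the signal was 54.7, 51.2 and 133 intensity units, against 424 to 653 on SSEA-1-positive-labelled and 1543 to 2904 on iPS-labelled arrays. Replicate 3 of the iPS-labelled and double-negative-labelled groups and replicate 1 of the SSEA-1-positive-labelled group were scanned on scan day 1 in a single range, and the other 6 arrays on scan day 2 in an extended range. Precision is limited by the number of arrays.

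**Figure D1:**
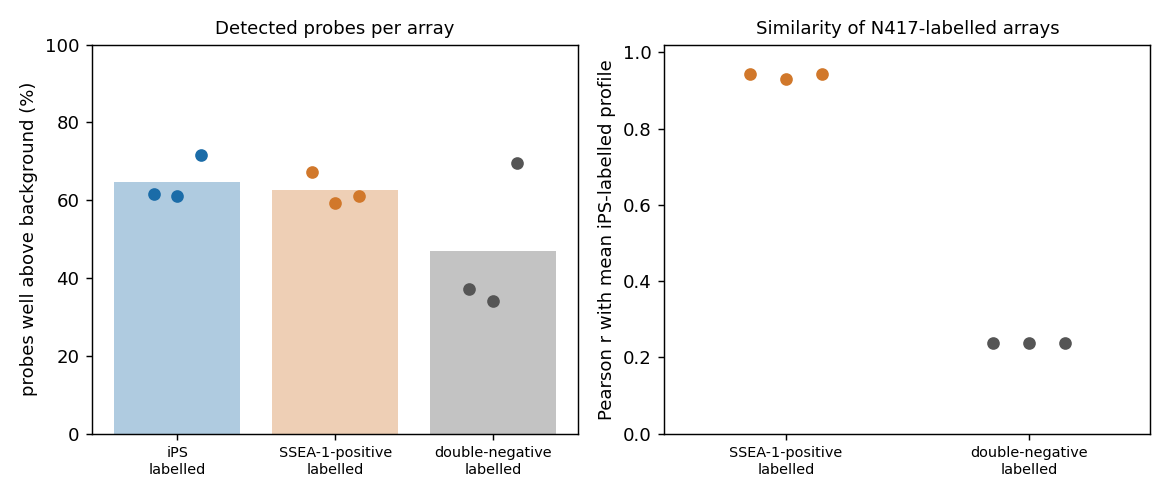
Left, percent of probes well above background on each array (points) and the mean of each labelled group (bars). Right, Pearson correlation across tested genes of each N417-labelled array with the mean iPS-labelled profile: the 3 SSEA-1-positive-labelled arrays lie at 0.931 to 0.944 and the 3 double-negative-labelled arrays at 0.237 to 0.238.

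Genes of the pluripotent state and of the sorted epitope were examined first, as a check of the labels. Levels are log2 signal minus the 75th percentile of the array, mean ± SD, n = 3 arrays per group. NANOG, a transcription factor of pluripotent cells, was not well above background on any of the 9 arrays. LIN28A, an RNA-binding protein of the same state, passed background on 1 double-negative-labelled array only. POU5F1, which encodes OCT4, stood at -4.59 ± 0.53 on iPS-labelled arrays (above background on 2 of 3), -2.22 ± 1.62 on SSEA-1-positive-labelled arrays and 1.78 ± 0.14 on double-negative-labelled arrays. It was thus lowest in the iPS-labelled group, by -6.37 ± 0.65 (SE) against double-negative-labelled arrays (limma adjusted p = 3.18e-06) and by -2.37 ± 0.65 against SSEA-1-positive-labelled arrays (limma adjusted p = 0.0436). The latter call was lost in 16 of 23 alternatives, and POU5F1 has near-identical gene copies that such probes can share. All 4 POU5F1 probes ordered the group means alike. The other 3 were above background on 1 of 3 iPS-labelled and at most 1 of 3 SSEA-1-positive-labelled arrays. Background alone gives this order at this scaling (NANOG -7.44, -6.27 and -3.40), so their order between those groups is no support. SOX2, a partner of OCT4, stood at -0.25 ± 0.36, 0.12 ± 0.31 and -0.98 ± 0.39 on iPS-, SSEA-1-positive- and double-negative-labelled arrays. Between the sorted fractions its level differed (limma adjusted p = 0.00981). It did not pass the test between iPS-labelled and SSEA-1-positive-labelled arrays (limma adjusted p = 0.533), nor against double-negative-labelled arrays (limma adjusted p = 0.061), while its second probe stood at 0.92 ± 0.36 on iPS-labelled and 0.94 ± 0.38 on SSEA-1-positive-labelled arrays and was not well above background on any double-negative-labelled array (-3.05 ± 0.36). KLF4, a reprogramming factor, was at -0.47 ± 0.15, -2.65 ± 0.11 and 1.73 ± 0.91, and MYC at 5.99 ± 0.15, 6.25 ± 0.18 and 1.55 ± 0.67. Of 38 members of the pluripotency list with a value on all 9 arrays, 14 were detected on all 3 iPS-labelled arrays, 16 on all 3 SSEA-1-positive-labelled arrays and 14 on all 3 double-negative-labelled arrays.

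FUT4, a fucosyltransferase that can complete the SSEA-1 epitope, stood at -0.52 ± 0.02 on SSEA-1-positive-labelled and -2.91 ± 0.52 on double-negative-labelled arrays, where 1 of 3 arrays detected it. The difference of 2.39 ± 0.32 (SE) passed the test (limma adjusted p = 3.37e-05), while the second FUT4 probe gave means of -3.06 and -2.79, in the opposite order. FUT9, the other fucosyltransferase of this step, stood at -2.23 ± 0.16 on SSEA-1-positive-labelled arrays and was not well above background on double-negative-labelled arrays (limma adjusted p = 0.00199). A second FUT9 probe gave the opposite order, with means of -4.38 (above background on 2 of 3 arrays) and -3.07 (1 of 3), and the remaining probe was at background in every group. No bound on the fold of FUT9 could be given, and its sign turned to -0.77 with the series matrix values and -0.78 with normexp. Between iPS-labelled and SSEA-1-positive-labelled arrays neither FUT4 (-0.28 ± 0.32, limma adjusted p = 0.629) nor FUT9 (-0.73 ± 0.32, limma adjusted p = 0.172) passed the test. NEUROD1, a neuroendocrine transcription factor of small cell lung cancer, was detected on every iPS-labelled and SSEA-1-positive-labelled array and on no double-negative-labelled array. B3GALT5, an enzyme of SSEA-3 synthesis, had no probe matched by name and was not analysed here.

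**Figure D2:**
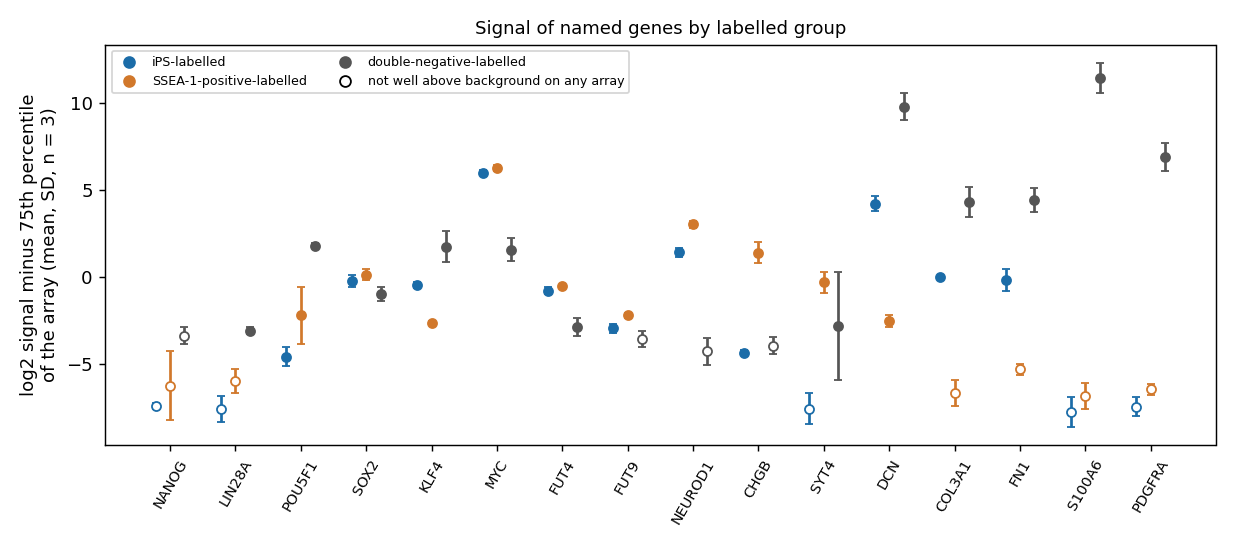
Log2 signal minus the 75th percentile of the array for 16 named genes in each labelled group (mean, SD, n = 3 arrays), with open circles where no array of the group was well above background. NANOG is open in every group, and S100A6 and PDGFRA are filled only in the double-negative-labelled group.

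Whether either sorted fraction lay nearer to the iPS-labelled arrays was examined across 13312 tested genes. The correlation with the mean iPS-labelled profile was 0.939 ± 0.0071 (SD, n = 3) for SSEA-1-positive-labelled arrays and 0.238 ± 0.00045 for double-negative-labelled arrays, across genes, which are not independent replicates. The root mean square difference from that profile was 1.04 ± 0.05 and 3.89 ± 0.22 log2 units. For both measures the exact permutation test gave a two-sided p of 0.1, the smallest that 3 arrays against 3 allow. Between single arrays the median correlation was 0.934 for iPS-labelled with SSEA-1-positive-labelled, 0.235 for iPS-labelled with double-negative-labelled and 0.277 for the sorted fractions with each other, against 0.968, 0.984 and 0.923 within the iPS-, SSEA-1-positive- and double-negative-labelled groups. Genes that differed between the sorted fractions and between iPS-labelled and all N417-labelled arrays overlapped: 4049 were higher in both (1745 for independent lists), 4741 lower in both (2365) and 242 opposite (4063). The changes correlated with r = 0.881 across genes (covariance 6.82), where orthogonal contrasts give a value near 0 without effects. With iPS-labelled arrays close to SSEA-1-positive-labelled ones, both contrasts hold the distance to the double-negative-labelled arrays, so the overlap is largely arithmetic.

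SSEA-1-positive-labelled arrays differed from double-negative-labelled arrays at most tested genes. BNIP3, a mitophagy receptor induced by hypoxia, was at least 736-fold higher in the SSEA-1-positive-labelled group, its probe being not well above background on any double-negative-labelled array (limma adjusted p = 8.87e-09). The same held for CTAG1A, which encodes the cancer-testis antigen NY-ESO-1 and has a near-identical copy, at least 510.5-fold higher, and for RPL22, a ribosomal protein, at least 446-fold. HERPUD1, of endoplasmic reticulum quality control, was at least 406-fold higher, malate dehydrogenase MDH1 at least 347-fold, thymidylate synthase TYMS at least 275-fold and the small nucleolar RNA host SNHG1 at least 246-fold. PCLAF, a PCNA-binding factor, and mitofusin MFN2 were at least 223-fold and 193-fold higher, all not well above background in the dimmer group. HILPDA, a lipid droplet protein, rose by 9.62 ± 0.43 log2 units (SE), with 1 of 3 double-negative-labelled arrays above background (limma adjusted p at most 4.27e-08 for these 9). In the opposite direction, the calcium-binding protein S100A6 was at least 73656-fold lower, DLK1 at least 16719-fold and AEBP1 at least 11784-fold lower in the SSEA-1-positive-labelled group, where none was well above background (limma adjusted p at most 9.06e-09). EMP3 and the Hippo pathway coactivator WWTR1 were at least 6400.4-fold and 5223-fold lower. TM4SF1, the growth factor receptor PDGFRA, the chemokine receptor CXCR3 and VASN were lower by at least 4419.5-fold, 3154-fold, 1682-fold and 1635-fold, and all 6 were not well above background (limma adjusted p at most 9.24e-09). Each bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The bounds hold for the scaling used here. With the 75th percentile over detected probes, 1.63 log2 units are added to every change between the sorted fractions, which makes bounds on falls 3.09-fold smaller and bounds on rises 3.09-fold larger. Of the 11078 called genes, 10854 had 3 arrays of the higher group above all 3 of the lower group.

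Lists fixed beforehand were then tested in the same comparison, with changes given as log2 ± SE, SSEA-1-positive-labelled minus double-negative-labelled. Of 29 measured G1/S phase genes, which serve DNA replication, 25 rose and 1 fell (camera adjusted p = 5.74e-06, and adjusted p = 0.415 with an estimated correlation). The replication licensing factor CDT1, ribonucleotide reductase RRM1 and helicase subunit MCM3 were at least 217-fold, 123-fold and 134-fold higher, not well above background in the double-negative-labelled group (limma adjusted p at most 2.37e-08). Of 28 G2/M phase genes, which serve mitosis, 19 rose and 7 fell (camera adjusted p = 0.0213, and adjusted p = 0.503 with an estimated correlation). Survivin, BIRC5, rose by 6.57 ± 0.29, with 1 of 3 double-negative-labelled arrays above background, and cyclin CCNB2 was at least 51.4-fold higher and not well above background in the dimmer group (limma adjusted p at most 1.43e-08). Of 23 cholesterol synthesis genes, 16 rose and 3 fell (camera adjusted p = 0.0129, and adjusted p = 0.415 with an estimated correlation). FDPS, farnesyl diphosphate synthase, rose by 7.30 ± 0.31 (limma adjusted p = 1.14e-08), with 1 of 3 double-negative-labelled arrays above background. Of 30 glycolysis and hypoxia genes, 19 rose and 9 fell (camera adjusted p = 0.0199, and adjusted p = 0.664 with an estimated correlation). Hexokinase HK2 and NDRG1 were at least 127-fold and 126-fold higher and not well above background in the dimmer group (limma adjusted p at most 9.88e-09).

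Other lists were lower in the SSEA-1-positive-labelled group. Some of these falls can be an offset of dim signal. NANOG, at background on all 9 arrays, stood at -3.40 ± 0.49 on double-negative-labelled and -6.27 ± 1.99 on SSEA-1-positive-labelled arrays at this scaling. Double-negative-labelled arrays detected 8 haematopoietic, 11 interferon response and 10 epithelial genes on all 3 arrays, fewer than the falls counted here. Of 30 fibroblast and mesenchymal genes, 22 fell and 3 rose (camera adjusted p = 0.00246, and adjusted p = 0.503 with an estimated correlation). The matrix proteoglycan decorin, DCN, fell by 12.31 ± 0.42 (limma adjusted p = 6.85e-09). The matrix protease MMP2 and the collagen COL3A1 were at least 1017-fold and 515-fold lower, not well above background on SSEA-1-positive-labelled arrays (limma adjusted p at most 1.53e-08). All 10 haematopoietic genes tested fell (camera adjusted p = 0.0142, and adjusted p = 0.415 with an estimated correlation). They included the monocyte receptor CD14 at -5.40 ± 0.44 and the T cell receptor component CD3E at -4.54 ± 0.33 (limma adjusted p at most 5.49e-07). Of 19 interferon response genes, 14 fell and 2 rose (camera adjusted p = 0.0199, and adjusted p = 0.415 with an estimated correlation). The antiviral enzyme RSAD2 was at least 84.3-fold lower and not well above background in the SSEA-1-positive-labelled group (limma adjusted p = 9.37e-08). Of 15 epithelial genes, 13 fell and 1 rose, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0213, and adjusted p = 0.415 with an estimated correlation). Among them were the splicing regulator ESRP2 at -4.67 ± 0.30 and the tight junction gene CLDN7 at -4.89 ± 0.82, detected on 1 of 3 SSEA-1-positive-labelled arrays (limma adjusted p at most 1.73e-04). Of 19 lung epithelium genes, 15 fell and 4 rose (camera adjusted p = 0.0411, and adjusted p = 0.503 with an estimated correlation). The surfactant protein gene SFTPC fell by 6.32 ± 0.29 (limma adjusted p = 1.52e-08). Podoplanin, PDPN, was at least 11.2-fold higher with double-negative-labelled arrays not well above background (limma adjusted p = 4.34e-08).

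The other 20 lists did not pass the list test in this comparison, though many members moved in each direction. For the epitope itself, 13 of 30 glycosylation genes rose and 12 fell (camera adjusted p = 0.679). The galactosyltransferase B4GALT1 was at least 38.3-fold higher and B4GALT6, of the same family, at least 11.1-fold lower, each with the dimmer group not well above background (limma adjusted p at most 1.20e-06). Of 22 neuroendocrine genes, 11 rose and 4 fell (camera adjusted p = 0.125). NEUROD1 was at least 33.7-fold higher and the prohormone convertase PCSK1 at least 44.8-fold lower, with dimmer groups not well above background (limma adjusted p at most 4.25e-08). INSM1, a neuroendocrine repressor, was at least 23-fold higher with double-negative-labelled arrays not well above background (limma adjusted p = 8.26e-08), while its other probe gave -0.69. Of 17 neuronal genes 8 rose and 7 fell (camera adjusted p = 0.69), and of 19 pluripotency genes 7 rose and 10 fell (camera adjusted p = 0.679). KLF4 stood at -4.38 ± 0.42 and FOXH1, a Nodal pathway factor, at -4.08 ± 0.35 (limma adjusted p at most 1.86e-06). Of 31 oxidative phosphorylation genes 16 rose and 11 fell (camera adjusted p = 0.0831). The cytochrome oxidase subunit COX6A1 rose by 8.59 ± 0.31 (limma adjusted p = 7.57e-09), and the SD of the change over the list was 4.13 log2 units. Of 36 ribosomal protein genes, a family with many near-identical copies, 6 rose and 25 fell (camera adjusted p = 0.125). Of 25 unfolded protein response genes 12 rose and 6 fell (camera adjusted p = 0.076). TRIB3, induced by that response, rose by 8.66 ± 0.50 and was detected on 1 of 3 double-negative-labelled arrays (limma adjusted p = 5.74e-08).

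Among signalling lists, higher and lower members numbered 8 and 10 of 20 for Notch (camera adjusted p = 0.679) and 6 and 15 of 24 for Wnt (camera adjusted p = 0.0767). They were 9 and 12 of 30 for TGF-beta, Nodal and BMP (camera adjusted p = 0.69) and 2 and 10 of 17 for Hedgehog (camera adjusted p = 0.0811). Among those that fell were the Notch target HES1 (-5.23 ± 0.44), the Wnt receptor FZD2 (-7.37 ± 0.46), the activin subunit INHBA (-10.34 ± 0.61) and the Hedgehog receptor PTCH1 (-4.98 ± 0.38) at limma adjusted p of at most 7.16e-07. For lineage lists the numbers were 2 and 11 of 15 for endoderm and mesoderm (camera adjusted p = 0.0692) and 2 and 11 of 19 for neuroectoderm (camera adjusted p = 0.239). The mesoderm factor TBXT stood at -4.24 ± 0.34 (limma adjusted p = 5.16e-07). Stress and growth lists gave 6 and 16 of 24 for immediate early genes (camera adjusted p = 0.202) and 7 and 8 of 20 for heat shock (camera adjusted p = 0.984). Counts were 10 and 7 of 23 for p53 targets and apoptosis (camera adjusted p = 0.548) and 12 and 8 of 29 for the MYC family and targets (camera adjusted p = 0.309). The small heat shock protein CRYAB stood at -8.90 ± 0.41, the growth-induced factor EGR1 at -5.69 ± 0.72 and the nucleolar protein NCL at 7.52 ± 0.38 (limma adjusted p at most 1.86e-05). Antigen presentation gave 3 and 13 of 18 (camera adjusted p = 0.152), cancer stem cell and drug efflux 3 and 9 of 15 (camera adjusted p = 0.308) and cancer-testis antigens 6 and 5 of 12 (camera adjusted p = 0.69). The HLA light chain B2M stood at -6.42 ± 0.45, the drug transporter ABCG2 at -11.28 ± 0.52, with 1 of 3 SSEA-1-positive-labelled arrays above background (limma adjusted p at most 2.07e-07). The cancer-testis gene MAGEA12 rose by 6.69 ± 0.37, with 1 of 3 double-negative-labelled arrays above background (limma adjusted p = 4.31e-08). Adjusted over the list alone, the counts were the same for every list but epithelial (above), Wnt, with 6 higher and 16 lower, and MYC family and targets, with 11 and 8. The list median and mean differed in sign for glycosylation (0.71 and -0.06, test up), TGF-beta, Nodal and BMP (0.20 and -1.11, test down) and heat shock (-0.83 and 0.08, test down).

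By limma, 11078 of 13312 genes passed an adjusted p of 0.05 between the sorted fractions, 5142 higher and 5936 lower in the SSEA-1-positive-labelled group, and 10801 of them by at least 2-fold. In 84.1% of all tested genes the 3 arrays of each group did not overlap, where chance gives 10% for 3 against 3. The count was 11170 with scan day as a block. No slide held both fractions, so with slide as a block (10156) the comparison runs through the iPS-labelled arrays and rests on 1 SSEA-1-positive-labelled and 2 double-negative-labelled arrays. Across all tested genes the changes within scan day 1 (1 array per group) and scan day 2 (2 per group) correlated with r = 0.931. The balance of directions rested on the scaling and on the filter of probes. The median change of all genes was -0.34 as scaled here, 0.17 after quantile normalization (5637 higher, 5453 lower), 0.13 with median scaling (5374 and 4913) and 1.29 with the 75th percentile taken over probes detected on all 9 arrays (6883 and 4208). The median was -0.66 with the series matrix values (4436 and 6950) and -0.66 with normexp (4294 and 6929). It was -2.02 with only probes above background on all 9 arrays (1030 and 4314) and -1.92 with no filter on dim probes (5081 and 9922). The list shifts on scan days 1 and 2 were 4.71 and 4.71 for G1/S phase, 2.24 and 2.14 for G2/M phase, 2.80 and 2.60 for cholesterol synthesis and 3.39 and 2.79 for glycolysis and hypoxia. They were -4.07 and -4.56 for fibroblast and mesenchymal genes, -3.46 and -3.53 for haematopoietic, -2.93 and -2.82 for interferon response, -2.64 and -2.51 for epithelial and -2.17 and -2.03 for lung epithelium genes. All 9 lists stayed under 0.05 with scan day as a block. With slide as a block and this 1 array, camera's adjusted p was 0.0647 for epithelial (range over 23 alternatives 0.00667 to 0.486) and 0.0821 for lung epithelium genes (0.0207 to 0.309). The shifts were then -2.28 in place of -2.56 and -2.03 in place of -2.07. With only probes above background on all 9 arrays, where fewer genes were tested, G1/S phase kept its call (camera adjusted p = 0.0166). Calls were lost for cholesterol synthesis (0.427), epithelial (0.486), fibroblast (0.309), lung epithelium (0.309) and G2/M phase genes (0.677). They were also lost for glycolysis (0.15) and haematopoietic genes (0.236). The highest value for interferon response was 0.0519, with quantile normalization. The double-negative-labelled arrays also stood apart at the level of probes. Genes accounted for a share of 0.194 of the variance of probe changes in this comparison and 0.51 between iPS-labelled and SSEA-1-positive-labelled arrays. The SD within genes was 2.90 and 0.547 log2 units.

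iPS-labelled arrays were compared next with SSEA-1-positive-labelled arrays, the comparison of iPS cells with the sorted positive fraction. Decorin, DCN, rose by 6.73 ± 0.42 log2 units (SE) and lumican, LUM, by 5.93 ± 0.45 (limma adjusted p at most 2.31e-05). The collagen COL3A1 and fibronectin FN1 were at least 25.9-fold and 21.2-fold higher, not well above background on SSEA-1-positive-labelled arrays (limma adjusted p at most 4.78e-05). LUM was detected on 2 of 3 SSEA-1-positive-labelled arrays. Chromogranin B, CHGB, stood at -5.74 ± 0.38 and SEZ6 at -4.87 ± 0.37, with SEZ6 detected on 1 of 3 iPS-labelled arrays (limma adjusted p at most 2.24e-05). Synaptotagmin SYT4 and secretogranin SCG2 were at least 37.4-fold and 12.5-fold lower, not well above background on iPS-labelled arrays (limma adjusted p at most 0.00662). NEUROD1 also fell, by 1.61 ± 0.39 (limma adjusted p = 0.0276). All 1377 called genes of this comparison had 3 arrays of 1 group above all 3 of the other.

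Of 22 neuroendocrine genes, 11 fell and 2 rose, or 12 and 2 adjusted over the list alone (camera adjusted p = 2.86e-05, and adjusted p = 0.201 with an estimated correlation). Of 17 neuronal genes, 6 fell, or 8 adjusted over the list alone (camera adjusted p = 2.80e-04, and adjusted p = 0.371 with an estimated correlation). Among them the RNA-binding proteins ELAVL3 and CELF3 changed by -3.38 ± 0.31 and -4.22 ± 0.57, CELF3 being detected on 1 of 3 iPS-labelled arrays (limma adjusted p at most 0.00104). Of 30 fibroblast and mesenchymal genes, 11 rose and 4 fell, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.586 with an estimated correlation). Of 24 immediate early genes, induced within minutes by growth factors or handling, 9 rose and none fell, or 10 adjusted over the list alone (camera adjusted p = 1.02e-04, and adjusted p = 0.586 with an estimated correlation). FOS rose by 3.08 ± 0.49 and EGR1 by 2.93 ± 0.72, and CCN2 was at least 3.81-fold higher, not well above background on SSEA-1-positive-labelled arrays (limma adjusted p at most 0.0276). Of 36 ribosomal protein genes, 10 fell, or 27 adjusted over the list alone (camera adjusted p = 2.02e-09, and adjusted p = 0.586 with an estimated correlation). RPL23 stood at -1.66 ± 0.41 and RPLP1 at -1.51 ± 0.38 (limma adjusted p at most 0.0311). The list median was -1.13, against -0.70 over the 68 other genes nearest in mean brightness and -0.52 over the 200 brightest other genes. The nearest genes were still dimmer, with a mean level of 6.91 against 7.89 log2 units for the list, so brightness was not matched. The call was lost after quantile normalization (camera adjusted p = 0.229, the highest over 23 alternatives, from 2.52e-18).

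Of 28 G2/M phase genes, 3 rose over all genes tested and adjusted over the list alone (camera adjusted p = 1.45e-04, and adjusted p = 0.549 with an estimated correlation). They were the centromere genes CENPA at 1.72 ± 0.42 and CENPE at 1.22 ± 0.33 and the mitotic kinase AURKA at 1.15 ± 0.30 (limma adjusted p at most 0.0414). Leaving out 1 array at a time ended these calls in 6, 7 and 6 of 9 runs, with changes of 1.51 to 1.84, 1.09 to 1.36 and 1.03 to 1.28. Interferon response genes rose at 5 of 19 members, or 6 adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.502 with an estimated correlation). ISG15 rose by 2.47 ± 0.38 (limma adjusted p = 0.00225), and the list shift of 0.70 turned to -0.0698 with normexp. Antigen presentation genes rose at 2 of 18 members by either adjustment, including adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.586 with an estimated correlation). The peptide transporter TAP1 rose by 3.76 ± 0.31 and the immunoproteasome subunit PSMB9 by 1.79 ± 0.36 (limma adjusted p at most 0.0103). Pluripotency genes fell at 4 of 19 members and rose at 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.425 with an estimated correlation). KLF4 rose by 2.18 ± 0.42 (limma adjusted p = 0.00776). This list call was lost in 12 of 23 alternatives (camera adjusted p 0.0096 to 0.458), among them slide as a block (0.122, with 1 array per group).

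The other 20 lists did not pass camera in this comparison, at adjusted p from 0.19 to 0.963. Single members with large changes were CRYAB, a heat shock protein, at 6.35 ± 0.41 and the desmosomal gene DSP at 4.01 ± 0.33, detected on 1 of 3 SSEA-1-positive-labelled arrays (limma adjusted p at most 4.33e-05). The mesendoderm factor GSC rose by 4.73 ± 0.52 and the cancer-testis gene MAGEA10 by 4.25 ± 0.58 (limma adjusted p at most 0.00108). Among signalling genes the Wnt receptor FZD8 rose by 3.08 ± 0.41 and the Notch targets HES1 and HES6 changed by 2.64 ± 0.44 and -1.99 ± 0.32 (limma adjusted p at most 0.00349). INHBA was at least 4.22-fold lower and not well above background on iPS-labelled arrays (limma adjusted p = 0.00241). The fucosyltransferase FUT1, which makes the H antigen, fell by 2.66 ± 0.68 (limma adjusted p = 0.0325), 1 of 2 glycosylation genes that fell, with none of 30 higher. Higher and lower members, in that order, were 4 and 1 of 24 for Wnt, 2 and 3 of 20 for Notch, 1 and 1 of 30 for TGF-beta, Nodal and BMP, and 4 and 1 of 17 for Hedgehog. Stress and growth lists had 2 and 2 of 20 for heat shock, 3 and 1 of 23 for p53 targets and apoptosis, 1 and 1 of 29 for G1/S phase, and 0 and 1 of 29 for the MYC family and targets. Metabolic and synthesis lists had 2 and 0 of 23 for cholesterol synthesis, 0 and 0 of 31 for oxidative phosphorylation (COX6C -1.27 ± 0.45, limma adjusted p = 0.0966), 0 and 0 of 25 for the unfolded protein response (ATF4 -0.91 ± 0.46, limma adjusted p = 0.235) and 2 and 1 of 30 for glycolysis and hypoxia. They were 2 and 0 of 12 for cancer-testis antigens, 1 and 2 of 15 for epithelial, 1 and 1 of 19 for lung epithelium, and 1 and 1 of 10 for haematopoietic genes. The rest had 2 and 3 of 15 for endoderm and mesoderm, 0 and 2 of 19 for neuroectoderm and 1 and 1 of 15 for cancer stem cell and drug efflux genes. Adjusted over the list alone these counts changed to 2 and 1 for cholesterol synthesis, 4 and 1 for p53 targets, 0 and 0 for G1/S phase and for the MYC family, and 2 and 2 for epithelial and for cancer stem cell genes. They became 2 and 4 for Notch and 2 and 3 for lung epithelium. Median, mean and test differed in sign for cancer-testis antigens (median -0.12, mean 0.41, test up), haematopoietic (-0.05, 0.17, up), glycosylation (0.12, -0.09, up) and glycolysis and hypoxia genes (-0.09, -0.02, up). Endoderm and mesoderm (median -0.45, mean -0.03) and lung epithelium genes (-0.19, -0.05) had a test down with shifts of 0.05 and 0.03.

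**Figure D3:**
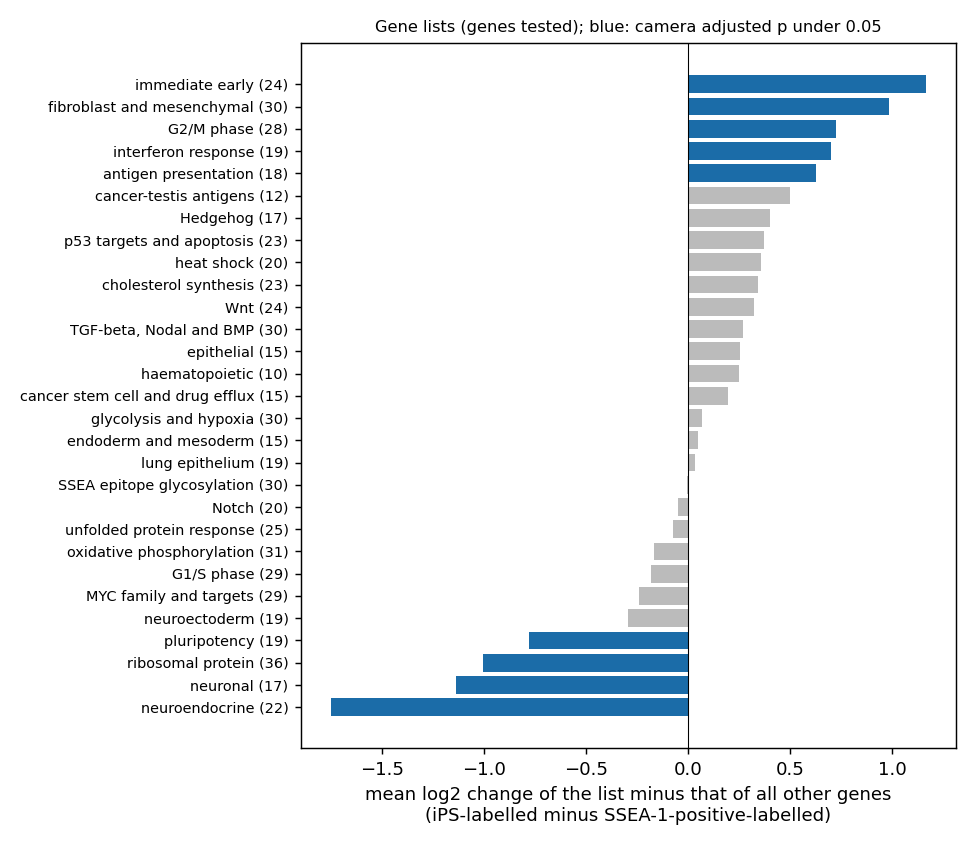
Mean log2 change of each of 29 gene lists minus that of all other tested genes, iPS-labelled minus SSEA-1-positive-labelled arrays (3 arrays per group), with the number of tested members in brackets and lists with a camera adjusted p under 0.05 at the preset correlation in blue. Immediate early genes lie highest at 1.16 and neuroendocrine genes lowest at -1.75.

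By limma, 1377 of 13312 genes passed between iPS-labelled and SSEA-1-positive-labelled arrays, 598 higher and 779 lower in the iPS-labelled group, and 1369 by at least 2-fold. In 53.5% of all tested genes the arrays of the groups did not overlap (10% by chance), 3532 genes had an unadjusted p under 0.05, and the median change was -0.08. The share of higher calls moved with the scaling, to 953 higher and 811 lower after quantile normalization (median 0.07), 392 and 177 with median scaling (0.29). It was 997 and 1147 when scaled by the percentile over detected probes (-0.04). The series matrix values gave 1775 and 3834 (-0.17) and normexp 1897 and 4262 (-0.19). The count was 1500 with scan day as a block. With slide as a block it was 377, which rests on the 1 slide that held both groups, with 1 array of each and the spread of the other arrays. Across all tested genes the changes within scan day 1 (1 array per group, which shared a slide) and scan day 2 (2 per group) correlated with r = 0.842. Leaving out 1 array gave 636 (without SSEA-1-positive-labelled replicate 3) to 4811 genes (without double-negative-labelled replicate 3, which enters through the shared spread, the background filter and the choice of probe). The shifts on scan days 1 and 2 were -1.94 and -1.66 for neuroendocrine, -1.10 and -1.15 for neuronal, 0.96 and 0.99 for fibroblast and mesenchymal, 1.24 and 1.13 for immediate early and -0.92 and -1.05 for ribosomal protein genes. For G2/M phase they were 0.57 and 0.81, for interferon response 0.79 and 0.66, for antigen presentation 0.70 and 0.59 and for pluripotency genes -0.53 and -0.91. With scan day as a block camera's adjusted p was 4.16e-05 for neuroendocrine, 0.0178 for fibroblast and 1.66e-04 for immediate early genes. Ranges over 23 alternatives were 1.42e-07 to 0.00394, 0.00132 to 0.285 and 1.59e-06 to 0.0032. The other 6 lists stayed under 0.05 with scan day as a block. The slide block gives the shifts of scan day 1 again and is no further evidence for these lists. Fibroblast, interferon and antigen presentation calls were lost in 5 of 23, 7 of 22 and 6 of 23 alternatives.

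iPS-labelled arrays were also compared with double-negative-labelled arrays, which the comparison of the sorted fractions holds too. INHBA, the activin subunit, was at least 5458-fold lower and PDGFRA at least 5609.9-fold lower, not well above background on iPS-labelled arrays (limma adjusted p at most 1.21e-08). BNIP3, NDRG1 and HK2 were at least 522-fold, 442-fold and 151-fold higher with double-negative-labelled arrays not well above background (limma adjusted p at most 1.13e-08). NEUROD1 was at least 11.1-fold higher in the iPS-labelled group with the double-negative-labelled arrays not well above background, and MYC rose by 4.44 ± 0.36 (limma adjusted p at most 4.54e-07). The second MYC probe had means of -3.55 on iPS-labelled arrays and -3.65 on double-negative-labelled arrays, where it was not well above background, and so did not show this rise. The surfactant gene SFTPC stood at -6.27 ± 0.29, CD14 at -5.64 ± 0.44 and the adhesion molecule CD44 at -5.99 ± 0.38 (limma adjusted p at most 3.44e-07). The stress-induced factor ATF3 was at least 190.2-fold higher, not well above background in the double-negative-labelled group (limma adjusted p = 1.13e-08). Of 29 G1/S phase genes 24 rose and 1 fell (camera adjusted p = 2.41e-05, and adjusted p = 0.562 with an estimated correlation). Of 28 G2/M phase genes 20 rose and 7 fell (camera adjusted p = 0.00867, and adjusted p = 0.635 with an estimated correlation). Cholesterol synthesis genes rose at 17 and fell at 4 of 23 (camera adjusted p = 0.00867, and adjusted p = 0.562 with an estimated correlation). Glycolysis and hypoxia genes rose at 18 and fell at 9 of 30 (camera adjusted p = 0.0272, and adjusted p = 0.708 with an estimated correlation). Fibroblast and mesenchymal genes fell at 22 and rose at 5 of 30 (camera adjusted p = 0.00867, and adjusted p = 0.682 with an estimated correlation). Haematopoietic genes fell at 9 of 10 (camera adjusted p = 0.025, and adjusted p = 0.562 with an estimated correlation). Ribosomal protein genes fell at 28 and rose at 6 of 36 (camera adjusted p = 0.0214, and adjusted p = 0.823 with an estimated correlation). This shift of -1.54 turned to 0.43 after quantile normalization. Adjusted over the list alone the counts were the same for all 29 lists, and the other 22 lists did not pass (camera adjusted p from 0.0623 to 1).

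By limma, 11185 of 13312 genes passed in this comparison, 5148 higher and 6037 lower in the iPS-labelled group, and 10912 of them by at least 2-fold. There was no overlap of arrays at 82.5% of tested genes (10% by chance) and at 10771 of the 11185 called genes. With the 75th percentile over detected probes, bounds on falls in this comparison are 3.16-fold smaller. The count was 11281 with scan day as a block and 11554 with slide as a block, which rests on the 2 arrays per group that shared a slide. Across all tested genes the changes within scan day 1 and scan day 2, whose 4 arrays of these groups shared a slide, correlated with r = 0.934. The median change of -0.46 moved to 0.22 after quantile normalization (5707 higher, 5468 lower) and 0.37 with median scaling (5722 and 4623). It was 1.20 when scaled by the 75th percentile over detected probes (6868 and 4335). The series matrix values gave -0.78 (4527 and 7071) and normexp -0.79 (4421 and 7075). With only probes above background on all 9 arrays it was -2.17 (974 and 4407), and with no filter on dim probes -2.11 (5102 and 10145). Within scan days 1 and 2 the shifts were 4.49 and 4.55 for G1/S phase, 2.80 and 2.95 for G2/M phase, 3.14 and 2.94 for cholesterol synthesis, 3.50 and 2.84 for glycolysis and hypoxia genes. They were -3.11 and -3.57 for fibroblast, -3.65 and -3.06 for haematopoietic and -0.65 and -1.98 for ribosomal protein genes. With slide as a block camera's adjusted p was 0.0914 for glycolysis and hypoxia (range over 23 alternatives 5.48e-04 to 0.152) and 0.0516 for haematopoietic genes (0.0029 to 0.249), with shifts of 2.84 in place of 3.06 and -3.06 in place of -3.25. It was under 0.05 for the other 5 lists on these 2 arrays per group. With only probes above background on all 9 arrays, where fewer genes were tested, none of these list calls held. Camera's adjusted p was then from 0.0764 (G1/S phase) to 0.494 (ribosomal protein). The ribosomal protein call was lost in 7 of 23 alternatives. Median and mean differed in sign for heat shock (median -1.43, mean 0.35, shift 0.65), MYC family (-0.19, 0.70, test up), glycosylation (0.48, -0.15, 0.14) and TGF-beta genes (0.04, -0.93, -0.63). For immediate early genes median, mean and test were down (-1.42 and -0.06), while the shift was 0.23.

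Genes that set the iPS-labelled arrays apart from both N417-labelled groups were taken from the contrast of iPS-labelled arrays with the mean of both, with a call required in each pairwise comparison too. The phospholipid-binding protein ANXA1 rose by 6.46 ± 0.46 log2 units (SE), with 2 of 3 SSEA-1-positive-labelled and 1 of 3 double-negative-labelled arrays above background (limma adjusted p = 2.24e-06). The hypoxia factor EPAS1 rose by 4.98 ± 0.34 and the selenium-binding protein SELENBP1 by 4.75 ± 0.46, each detected on 1 of 3 double-negative-labelled arrays (limma adjusted p at most 8.05e-06). The small heat shock protein HSPB2 was not well above background on any N417-labelled array, and was at least 50.6-fold higher than on SSEA-1-positive-labelled and at least 8.02-fold higher than on double-negative-labelled arrays (limma adjusted p = 1.51e-06 against both). For 6 more genes that rose, the double-negative-labelled arrays were not well above background, so changes are given against the SSEA-1-positive-labelled group with a bound for the other. LUM rose by 5.93 ± 0.45 (at least 21.5-fold) and SCRG1 by 5.04 ± 0.31 with 1 of 3 SSEA-1-positive-labelled arrays above background (at least 5.38-fold), the bounded group being not well above background (limma adjusted p against both at most 1.50e-06). The secreted protease HTRA1 rose by 3.55 ± 0.36 (at least 30.6-fold), the bounded group being not well above background (limma adjusted p against both at most 1.47e-06). NDRG1 rose by 1.81 ± 0.30 (at least 442-fold), the autophagy protein MAP1LC3B by 1.78 ± 0.43 (at least 53.7-fold) and the nucleolar helicase DDX21 by 1.54 ± 0.42 (at least 56.1-fold), again with that group not well above background (limma adjusted p against both at most 2.91e-06).

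INHBA, the mitochondrial co-chaperone DNAJC15 and the glutamate transporter SLC17A6 were not well above background on any iPS-labelled array. They were at least 4.22-fold, 3.2-fold and 19.2-fold lower there than on SSEA-1-positive-labelled arrays, being not well above background (limma adjusted p in the contrast with both groups at most 1.48e-06). The collagen COL1A2 stood at -7.74 ± 0.39 and the matrix protein EFEMP2 at -6.52 ± 0.37 against the mean of both groups, each detected on 2 of 3 iPS-labelled arrays (limma adjusted p at most 1.47e-06). Here and for the falls that follow, such a change is an average over both groups and not the distance from either. The guidance cue NTN1 fell by 6.04 ± 0.37 (limma adjusted p = 1.48e-06). Detected on 1 of 3 iPS-labelled arrays were the sarcoglycan SGCD at -5.87 ± 0.36, the proteoglycan BGN at -5.59 ± 0.33, the scaffold protein NBEA at -5.46 ± 0.52 and FLRT3 at -5.43 ± 0.39 (limma adjusted p at most 6.81e-06). These genes were taken from called genes whose iPS-labelled arrays lay above or below all 6 N417-labelled arrays, which held for 3878 of the 9822 called genes. Of the genes named in every comparison, POU5F1 (-4.37 ± 0.57) fell and MYC (2.09 ± 0.31), FUT4 (0.91 ± 0.28) and NEUROD1 (2.04 ± 0.34, with double-negative-labelled arrays not well above background) rose against the mean of both groups (limma adjusted p at most 0.0124). Against the SSEA-1-positive-labelled group alone MYC, FUT4 and NEUROD1 stood at -0.26 ± 0.36, -0.28 ± 0.32 and -1.61 ± 0.39, so these rises reflect the double-negative-labelled arrays. The second MYC probe did not rise in this way (-3.55 on iPS-labelled, -2.57 on SSEA-1-positive-labelled and -3.65 on double-negative-labelled arrays), nor did the second FUT4 probe (-4.42, -3.06 and -2.79). SOX2 (0.18 ± 0.29), KLF4 (-0.01 ± 0.36) and FUT9 did not pass (limma adjusted p at least 0.582).

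By limma 9822 of 13312 genes passed in that contrast, 4518 higher and 5304 lower, with 9043 by at least 2-fold, no overlap of arrays at 29.7% of tested genes and a median change of -0.23. The count was 10004 with scan day as a block and 10574 with slide as a block, where only 1 SSEA-1-positive-labelled array informs it. The median moved to 0.15 after quantile normalization (4923 higher, 4760 lower) and 0.37 with median scaling (5156 and 3224). It was 0.62 when scaled by the percentile over detected probes (5966 and 3854). The series matrix values gave -0.42 (4177 and 6459) and normexp -0.44 (4099 and 6556). G1/S phase genes rose at 21 and fell at 1 of 29 (camera adjusted p = 1.68e-04, and adjusted p = 0.537 with an estimated correlation). G2/M phase genes rose at 19 and fell at 3 of 28 (camera adjusted p = 0.00186, and adjusted p = 0.537 with an estimated correlation). Cholesterol synthesis genes rose at 16 and fell at 3 of 23, or 17 and 3 adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.537 with an estimated correlation). Ribosomal protein genes fell at 29 and rose at 5 of 36 (camera adjusted p = 0.00234, and adjusted p = 0.69 with an estimated correlation). Glycolysis and hypoxia genes rose at 18 and fell at 8 of 30, or 18 and 9 adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.681 with an estimated correlation). Because the mean of both groups holds the double-negative-labelled arrays, these 5 lists were also past the threshold against that group alone, and of them only ribosomal protein and G2/M phase genes passed against the SSEA-1-positive-labelled group. The other 24 lists did not pass (camera adjusted p from 0.064 to 0.983). Median and mean differed in sign for MYC family (-0.28 and 0.19, test up), TGF-beta (0.14 and -0.37, test up) and glycosylation genes (0.05 and -0.12, test up).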

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

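Every test of an explanation in this part was chosen after the result was seen, and the counts over other splits of the arrays were planned. On 4 spike-in control probes, which no comparison uses, the mean log2 signal was 15.37 on scan day 1 and 10.49 on scan day 2, a difference of 4.88, and on each day the double-negative-labelled arrays lay between the other groups. Among 7354 kept probes without a matched gene name, 987 changed between iPS-labelled and SSEA-1-positive-labelled arrays (limma adjusted p under 0.05), 185 higher and 802 lower. Groups of 3 arrays were not tested for single arrays far from the others.

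The double-negative-labelled arrays were unlike all others, although the labels make them a fraction of the same line as the SSEA-1-positive-labelled ones. Too little labelled RNA would dim probes while keeping their order, but over the 10308 probes detected on all 9 arrays the median Spearman correlation with SSEA-1-positive-labelled arrays was 0.420, against 0.946 between iPS-labelled and SSEA-1-positive-labelled arrays. Another intact population of the N417 line would keep the proportions of genes that every cell uses, which argues against it as the whole cause, since the changes over the oxidative phosphorylation list had an SD of 4.13 log2 units (0.543 between iPS-labelled and SSEA-1-positive-labelled). RNA that binds only some probes of a gene, such as degraded RNA or RNA of another organism, is a candidate explanation: over 3740 genes with several probes, genes accounted for a share of 0.194 of the variance of probe changes, against 0.51 between iPS-labelled and SSEA-1-positive-labelled arrays, where it was thus also far from complete. The SD within genes was 2.90 and 0.547 log2 units. Over 1170 genes with several probes detected on all 9 arrays, where dim signal plays less part, the shares were 0.288 and 0.570. These sources were not told apart, and a biological difference between the sorted fractions stays open as a part of the pattern.

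The iPS-labelled arrays resembled SSEA-1-positive-labelled arrays and detected on all 3 arrays 14 of the 38 pluripotency genes with values, without NANOG and LIN28A. A swap of labels between groups would put the pluripotency list in an N417-labelled group. SSEA-1-positive-labelled arrays detected 16 of its 38 members with values, which argues against a swap with that group. Double-negative-labelled arrays detected 14, where the count cannot decide, since only 13474 of 41000 probes were detected there. Of 19 tested members, 11 were higher and 5 lower there than on iPS-labelled arrays. Dim signal also reads higher there at this scaling, but these 11 were well above background on all 3 double-negative-labelled arrays. ESRRB, LEFTY1 and SALL4 were detected on all 3 of those and on no iPS-labelled array, at least 23.7-fold, 25.6-fold and 19.9-fold higher. LIN28B and PHC1 were detected on all 3 iPS-labelled arrays and on no double-negative-labelled array. A swap with the double-negative-labelled group thus stays open. Low sensitivity is argued against by 674 more probes detected on all 3 iPS-labelled than on all 3 SSEA-1-positive-labelled arrays. A wrong label or an outside sample of the N417 kind stays open. On all 3 iPS-labelled arrays 11 of 20 cancer-testis antigen genes were detected, against 10 on SSEA-1-positive-labelled and 7 on double-negative-labelled arrays. This count cannot decide, since 23889 of all 41000 probes were detected on all 3 iPS-labelled arrays, a similar share. Loss of the pluripotent state in culture was not tested and stays open.

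Compared with SSEA-1-positive-labelled arrays, the fibroblast and mesenchymal list was higher on the iPS-labelled ones (11 of 30 genes rose and 4 fell) and the neuroendocrine list lower (11 of 22 fell and 2 rose). Both calls rest on camera's preset correlation and were lost at an estimated one (camera adjusted p = 0.586 and 0.201), and the mesenchymal call was lost in 5 of 23 alternatives. A large admixture of RNA of the double-negative-labelled kind would bring most of its bright transcripts. Of the 200 genes brightest there, among those at background on SSEA-1-positive-labelled arrays, 58.5% were at background on every iPS-labelled array. This argues against a large admixture only. The test set no admixed share, and a small admixture, which could bring only the most abundant transcripts, stays open. Scan day is argued against as the whole cause, since each day held every group and 4 of 4 shifts of these lists within the scan days kept their sign. A difference between the cells, whether of line or of state, may remain. Per the labels' protocols, culture medium also differed between iPS and N417 cells, and antibody isolation is given for the N417 fractions. No test here separates line, state, medium and isolation.

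Other splits of the same arrays were counted for each comparison. In each pairwise comparison the 10 splits of 6 arrays are too few for a share under 0.05: the real split called 11078, 1377 and 11185 genes for SSEA-1-positive against double-negative, iPS against SSEA-1-positive and iPS against double-negative, and the highest other split 0, 1 and 0, so that 1 split, the real one, gave as many in each. With iPS-labelled against all N417-labelled arrays as 2 groups, the real split called 105 genes and 2 of 84 splits gave as many. This cannot decide on chance, since arrays of a group resemble each other and every split that mixed groups called 0 genes. The split of SSEA-1-positive-labelled arrays against the rest called 7. The highest other split, double-negative-labelled against the rest, called 11001 genes, which points to a structure of the samples in which that group stands apart.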

How the results depend on the processing

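The following 3 alternatives were added after seeing the data, namely the percentile over detected probes, normexp on median signals and scan day 2 alone, and normexp on mean signals was not run for want of that column. Of 5662 values of named genes under alternatives, 5166 kept direction and side of the threshold, 460 were no longer past it, 22 passed it newly and 14 reversed; of 2085 list values the numbers were 1922, 93, 68 and 2. The similarity difference of 0.702 lay between 0.460 (probes above background on all 9 arrays) and 0.741 (quantile). With probes above background on all 9 arrays fewer genes were tested, and the counts fell to 5344 (SSEA-1-positive against double-negative), 545 (iPS against SSEA-1-positive), 5381 (iPS against double-negative), 4548 (iPS against both), 4135 for the overlap, 9 list calls in place of 25 and 64 called named genes in place of 235. With every kept probe tested they were 20827, 2914, 21242, 18620 and 16002. At an estimated correlation 0 lists passed by camera.

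The comparison of iPS-labelled with SSEA-1-positive-labelled arrays moved most, from 1377 genes to 569 with median scaling, 5609 with the series matrix values, 2144 with detected probes, 6159 with normexp, 377 with slide as a block (1 array per group), 2575 on scan day 2 and 4295 with only the groups compared, where the double-negative-labelled arrays no longer enter the shared spread. Leaving out 1 array gave 735, 694 and 761 without iPS-labelled replicates 1 to 3, 663, 653 and 636 without SSEA-1-positive-labelled ones, and 4811 without double-negative-labelled replicate 3.

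Ribosomal protein genes against double-negative reversed to 0.43 with quantile normalization and interferon genes (iPS against SSEA-1-positive) to -0.0698 with normexp. In the latter comparison, with series matrix values and normexp, ABCC3 turned to -0.17 and -0.39, GLI3 to -0.19 and -0.52, FOXF1 to -0.25 and -0.50, MEIS2 to 0.12 and 0.0541, IFIT3 to -0.54 and -0.72, and IFIT2 to -0.34 with normexp. Between the sorted fractions FUT9 turned to -0.77 and -0.78. For these the cause was not tested. INSM1 turned to -0.69 with probes above background on all 9 arrays, where a probe that disagrees took the place of the first.

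Replicate numbers did not pair the arrays: 0 of 9 same-number pairs correlated over 0.1 (-0.26 to 0.04). With the replicate block the counts were 10997, 1060, 11116 and 9712, and 17 gene calls and 0 list calls changed. Dim signal limits the double-negative-labelled values, where many genes have only a bound.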

Other observations

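Detection, a well-above-background call on all 3 arrays of a group, needs no scaling and was counted for the members of each list with a value on all 9 arrays. Over all 41000 probes it held for 23889 in the iPS-labelled, 23215 in the SSEA-1-positive-labelled and 13474 in the double-negative-labelled group, so lower counts in the last group are expected for any list. All 29 such G1/S phase and all 28 such G2/M phase genes were detected in the iPS-labelled and the SSEA-1-positive-labelled groups, against 10 and 11 in the double-negative-labelled group. Of 24 cholesterol synthesis genes, 23 were detected in each of the former groups and 10 in the double-negative-labelled group. Ribosomal protein genes were detected at 36, 36 and 35 of 36 in the iPS-, SSEA-1-positive- and double-negative-labelled groups. Epithelial genes were detected at 14 of 27 in the iPS-labelled group, 7 in the SSEA-1-positive-labelled group and 10 in the double-negative-labelled group, and haematopoietic genes at 9, 5 and 8 of 23. Interferon response genes were detected at 13, 9 and 11 of 27, and cancer-testis antigens at 11, 10 and 7 of 20. These are counts of genes, for which no test was run.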
